A study of Homo sapiens with 154 samples.

How the data were processed

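Per the labels' protocols, genomic DNA of live cells was extracted with a column kit and that of fixed cells with phenol and chloroform, and the sgRNA cassette was amplified by PCR. The deposited values were counts of reads per guide in the sublibrary screen and counts of reads per pair of guide and barcode in the CD54 screen. Per the submitters' processing notes, the authors used R 4.5.0, MAGeCK 0.5.7 and the hg38 assembly; how reads were assigned to guides is not stated there. The values were whole numbers with no scaling, so they were used as counts.

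The labels describe 154 samples. Of these 108 are sublibrary libraries, 36 are sorted CD54 libraries and 1 is the plasmid library of the CD54 screen, and 9 samples sequenced on a MiniSeq were not used here, since no column could be assigned to them. The sublibrary holds 2552 guides for 792 genes, of which 650 have 3 guides, 90 have 2 and 1 has 1, and 129 negative control guides. Reads per library ran from 199816 to 12247218: 2522785 to 12247218 with constant cells, 509769 to 7420540 with constant sgRNA and 199816 to 5836269 in the low MOI control. Guides without a read made up at most 5.76%, 19.6% and 48.7% of a library in these arms. The CD54 table holds 883714 pairs, and each string of 30 bases was split into a guide of 19 bases and a barcode of 11 bases by the position where the number of distinct strings falls to 41. Each of 20528 targets (18901 gene symbols) and 1026 controls has 1 guide with 41 barcodes, so a target's count is the sum over its barcodes. Sorted libraries had 19307560 to 27127871 reads at MOI 0.3 and 30838820 to 54798401 at MOI 5, and no guide was at 0. Targets were matched to current RefSeq symbols (17438) or through 1 older name (1295), and those of the sublibrary likewise (688 and 96). Of the targets, 352 share 170 guides, 149 of which carry the same counts under each name, and 33 whose names had become calendar dates are not named. Of 2423 sublibrary guides 692 match CD54 guides as the reverse complement and 0 on the same strand, which gave the end next to the PAM.

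Counts were summed over the guides of a gene and tested with edgeR 4.0.16 (quasi-likelihood F test, robust, R 4.3.3, limma 3.58.1), with filterByExpr at a minimum count of 10 and the Benjamini-Hochberg adjusted p of 0.05 as threshold. Library scaling was TMM over the control guides, which were kept out of the gene tests. The DMSO effect is day 14 in DMSO minus day 0, and the imatinib effect is day 14 in imatinib minus day 14 in DMSO. The constant cells effects are means over 7 MOIs from 1 fit of 42 libraries with a mean per group. Slopes are changes per doubling of labelled MOI. Each of 18 conditions was also fitted alone (6 libraries), the arms were compared in 1 fit of 90 libraries at MOI 2.5 to 30, and the CD54 effects are means over 3 coverages from 18 libraries per MOI and from all 36 for the difference. To measure how often guides without a target pass, control guides were drawn into 43 pseudo-genes of 3 guides in the sublibrary and tested singly in the CD54 screen. The scale of the sublibrary is uncertain, since control guides gained on the median gene over 14 days, so splits under other scalings stand beside the main ones.

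Comparisons, alternatives, the gene lists (42) and the rule for named genes were written down in advance. For the effects of DMSO, imatinib and the CD54 gates the rule took the 10 largest rises and falls that passed and had 1 sign at every MOI or coverage, for slopes and the MOI difference the 5 smallest p-values each way, for the arms the 3 smallest each way, ICAM1 in each CD54 result and up to 4 members per list with the smallest p. Only 5 falls with imatinib met it. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over lists, and members were also adjusted over the list alone. The results of 1 gene and 1 list are not reported here.

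The tests of both constant cells means and slopes, 1 arm difference (DMSO, low MOI control minus constant cells), 3 single conditions (DMSO with constant cells at MOI 0.3 and in the low MOI control at MOI 30, CD54 at MOI 0.3 and 25x), the CD54 effects of high against low and their difference between MOIs were checked on simulated data. So were the guide-level test, rank aggregation, means of guide log2 values and DESeq2 for the DMSO mean. The other arm differences, the other single conditions, the comparisons with the middle gate and the barcode-set test were not simulated. In each simulation 200 genes were changed by known folds in counts drawn from the real means and library sizes. Guides, or barcode sets in the CD54 screen, were drawn separately with the spread of the gene sum and changed equally. Simulated gene sums thus varied less than real ones, so the shares found may be too high and the false calls too few. Among real controls 9 of 43 pseudo-genes passed for DMSO and 106 of 1026 guides for CD54 at MOI 0.3. Changes of 0.5, 1 and 2 log2 units were found in 94.0%, 100% and 100% of genes for the DMSO effect with 3 false calls, 88.1%, 98.5% and 100% for imatinib, and 88.1%, 100% and 100% for CD54 at MOI 0.3. For the difference between MOIs they were found in 77.6%, 100% and 100% with 13 false calls, and for CD54 at MOI 0.3 and 25x in 8.96%, 55.2% and 100%. Slopes of 0.15, 0.3 and 0.6 were found in 59.7%, 98.5% and 100% with DMSO and 67.2%, 94.0% and 100% with imatinib. Arm differences of 1, 2 and 4 log2 units were found in 58.2%, 94.0% and 100% with 9 false calls, and the single condition at MOI 0.3 found 17.9%, 70.2% and 97.0% of changes of 0.5, 1 and 2. Of 2 simulated lists of 20 genes, camera called the raised list and not the unchanged list.

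Alternatives planned were TMM over all guides, relative log expression factors, no filter, a replicate block, each replicate, MOI or coverage left out, a guide-level test (2 guides in 1 direction), each gene without its most-counted guide, DESeq2 1.42.0, rank aggregation of guide p-values in the manner of MAGeCK (alpha 0.25, 1e+06 draws), MOI as rank, and distinct barcodes in place of reads. In the CD54 screen the 4 sets of barcodes by first base took the place of guides. Alternatives added after seeing the data were the summed control reads as scale, counts beyond the range of the controls, p-values ranked against the controls, means of guide or barcode log2 values in limma, and the arms without MOI 20 and 30. Labels were regrouped 100 times in the sublibrary and 50 or 30 times in the CD54 screen. Permutation tests drew 10000 times (seed 20240). Files were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and version 1.17.8 of data.table, and plots drawn with matplotlib 3.10.9.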

Results

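Human K-562 leukaemia cells, a line driven by the BCR-ABL fusion kinase, were infected with pooled CRISPR interference (CRISPRi) libraries at rising multiplicity of infection (MOI), so that a cell carried from less than 1 to many single guide RNAs (sgRNAs). The growth screen used a sublibrary of 2552 guides against 792 genes, most of them regulators of chromatin and transcription, with 129 negative control guides. Cells were sampled at day 0 and after 14 days in DMSO or in 230 nM imatinib, an inhibitor of the ABL kinase. Each group had 2 libraries. The DMSO effect below is the change from day 0 to day 14 in DMSO. It does not measure an effect of DMSO itself, since the labels give no day 14 group without DMSO or imatinib. The labels describe 3 arms. The constant cells arm kept the number of cells fixed while the MOI went from 0.3 to 30 (42 libraries). Another kept the number of sgRNA integrations fixed (constant sgRNA, 30 libraries), and the last was a low MOI control (36 libraries). The labels give this control MOIs of 1 to 30 without saying whether these are its own or those of the conditions it was set beside, so they are used below only as names. A separate screen stained cells for CD54, the adhesion protein encoded by ICAM1, and sorted high, middle and low gates at MOI 0.3 and 5 and at 25, 125 and 250 times coverage, which gave 36 libraries over 20528 targets. Guide counts were read as the share of cells that carried each guide, so a gene that fell is one whose repression was depleted. The p-values below measure only the spread between these libraries, which may be technical. Values are log2 fold changes with standard errors, and the number after them or alone in parentheses is the adjusted p.

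Over 14 days in DMSO, guides against PAF1, PRPF31, KANSL2 and TTK left the constant cells population most strongly. PAF1, the scaffold of the PAF1 elongation complex, fell by 5.29 ± 0.42 log2 units (mean over 7 MOIs, 14 against 14 libraries, adjusted p = 3.2e-12). PRPF31, a splicing factor of the tri-snRNP, fell by 5.07 ± 0.36 (3.8e-13), and TTK, a kinase of the spindle checkpoint, by 4.93 ± 0.39 (3.0e-12). KANSL2 and KANSL3, subunits of the NSL histone acetyltransferase complex, fell by 4.96 ± 0.18 (5.4e-20) and 4.46 ± 0.22 (7.3e-17). The splicing factor SRSF1 fell by 4.87 ± 0.24 (5.8e-17), the actin-like chromatin remodelling subunit ACTL6A by 4.83 ± 0.53 (2.3e-09). The TFIID and SAGA subunit TAF12 fell by 4.66 ± 0.32 (1.8e-13), the histone chaperone CHAF1B by 4.65 ± 0.38 (8.2e-12) and topoisomerase TOP2A by 4.43 ± 0.35 (3.3e-12). The thinnest groups of ACTL6A and TOP2A held only 2 and 8 reads, so their sizes are uncertain. Rises were smaller. The coactivator NCOA6 gained 0.82 ± 0.14 (9.0e-06), the histone acetyltransferase CREBBP 0.79 ± 0.14 (1.9e-05), the zinc finger protein ZMYM2 0.55 ± 0.11 (5.5e-05) and HIRIP3, a partner of the histone chaperone HIRA, 0.52 ± 0.07 (5.2e-07). Values between 0.36 and 0.44 were reached by HMGN4 (0.44 ± 0.09), the kinase TSSK6 (0.41 ± 0.10), BRD1 (0.40 ± 0.14), the histone methyltransferase KMT2C (0.38 ± 0.12), EID1 (0.37 ± 0.10) and the translocase HLTF (0.36 ± 0.14). RB1, the retinoblastoma cell cycle brake, rose by 0.53 ± 0.22 (0.047).

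Among the gene lists written before the data were examined, those of the core transcription and cell division machinery were depleted throughout. All 9 genes of RNA polymerase and general transcription fell (list median 3.16 log2 units below the median of all genes, camera adjusted p = 4.7e-09). Among them were the TFIID subunits TAF8 (−4.13 ± 0.14), TAF7 (−3.28 ± 0.12), TAF2 (−4.03 ± 0.19) and TAF1 (−3.28 ± 0.22). The 9 integrator and exosome genes, of RNA 3' end processing and decay, all fell (3.60 below, 9.6e-05), with EXOSC4 at −4.15 ± 0.22 and EXOSC6 at −3.84 ± 0.24. So did all 5 spliceosome genes (4.0 below, 0.0015), SF3B1 at −2.63 ± 0.17 and SRSF3 at −4.12 ± 0.49 among them. All 8 genes of the cell cycle engine fell (2.56 below, 0.0015), with the CDK-activating kinase CDK7 at −2.91 ± 0.11, AURKA at −2.46 ± 0.20 and the checkpoint kinase BUB1 at −2.35 ± 0.20. Adjusted over the list alone, the counts of these 4 lists were the same. In the MLL and menin complex, which methylates histone H3 lysine 4, 11 of 17 fell, 3 rose and 3 did not pass (1.45 below, 0.0084, 12 fell adjusted over the list alone). CXXC1 (−3.33 ± 0.13), SETD1A (−2.22 ± 0.12) and DPY30 (−2.57 ± 0.16) fell.

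Other chromatin complexes had many depleted members without differing from the remaining genes as a list. In the SAGA and ADA acetyltransferases 15 of 20 fell, 1 rose and 4 did not pass (camera adjusted p = 0.20), with TRRAP at −4.38 ± 0.15, TAF9 at −2.72 ± 0.20 and TAF5L at −1.23 ± 0.10. BAF chromatin remodelling had 11 falls, 2 rises and 7 that did not pass of 20 (0.94), BRD9 at −1.70 ± 0.11 and SMARCE1 at −1.71 ± 0.16 among the falls. Histone deacetylase and demethylase corepressors had 15 falls and 2 rises of 32 (0.48), with SIN3A at −1.72 ± 0.09 and CHD4 at −2.74 ± 0.17. PRC2 and HUSH silencing had 7 falls and 1 rise of 14 (0.94), with RBBP4 at −2.90 ± 0.17 and EZH2, the H3 lysine 27 methyltransferase, at −1.08 ± 0.09. The PRC2 list had a negative median and mean (−0.15 and −0.56) while its test leaned upwards. With TMM over all guides the medians of PRC2 (0.19) and of the corepressors (0.08) were positive. The rises and falls were then 7 and 5 for PRC2, 9 and 12 for corepressors, 9 and 6 for BAF, 5 and 11 for SAGA, and 4 and 11 for the MLL complex. Of 4 measured genes in the list of erythroid transcription factors 3 fell (0.24): GFI1B (−1.92 ± 0.14), IKZF1 (−0.97 ± 0.08) and MAX (−3.05 ± 0.46). The thinnest group of MAX held only 17 reads, so the size of its fall is uncertain. All 3 genes of the KEAP1 and CUL3 ubiquitin ligase fell (0.32): RBX1 (−1.92 ± 0.16), CUL3 (−1.86 ± 0.25) and KEAP1 (−0.82 ± 0.21). So did the 3 DNA replication genes (0.051), CDC6 at −2.48 ± 0.17 and PCNA at −1.90 ± 0.26 among them. In ubiquitin-like conjugation 5 of 8 fell (0.36), including the cullins CUL2 (−4.12 ± 0.21) and CUL1 (−2.56 ± 0.32). The 3 genes of NF-kB signalling, MAP3K7, CHUK and UBE2N, did not pass (0.25, 0.08 and −0.06), but with TMM over all guides MAP3K7 (0.58) and CHUK (0.42) rose. For the PRC2, corepressor, BAF, SAGA, MLL, KEAP1, erythroid, replication and ubiquitin lists, the counts adjusted over the list alone differed from these only in the MLL complex.

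In edgeR's quasi-likelihood test 379 of 792 genes passed a Benjamini-Hochberg adjusted p of 0.05, 56 higher and 323 lower. Rank aggregation of guide p-values gave only 1 gene. The share of rises depends on what is taken as unchanged: with TMM scaling over all guides 339 rose and 250 fell, and with relative log expression factors 337 and 250. With the summed control reads as scale, a setting added after seeing the data, 10 rose and 386 fell. These scalings moved the median of all genes, −0.12, by 0.33, 0.33 and −0.16. Of 43 pseudo-genes made from control guides 9 passed, with a median of 0.14, so the rises lie close to this background. Of the genes past the threshold, 227 (12 higher, 215 lower) lay beyond every pseudo-gene, CREBBP among the rises. With 792 genes and only 43 pseudo-genes, as few as 12 rises can lie there without effects. The largest rise, NCOA6, turned to −0.29 without its most-counted guide. All 5 list calls held with an estimated correlation, with camera adjusted p from 2.1e-05 to 0.027.

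**Figure D1:**
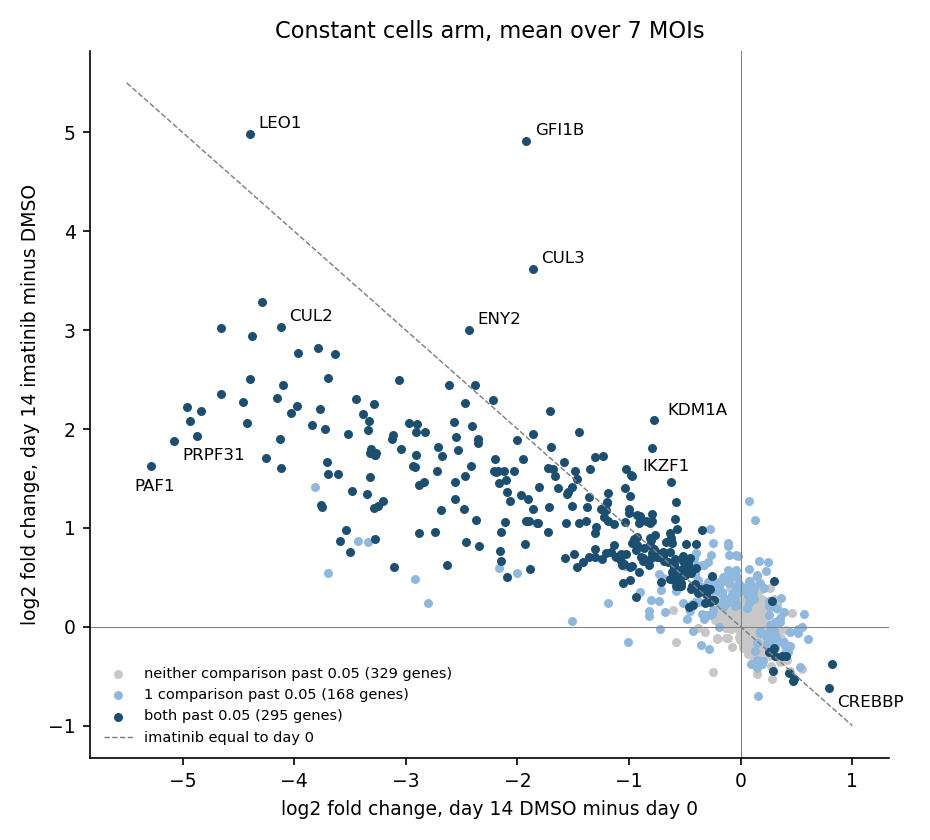
Change of each gene over 14 days in DMSO against its change between imatinib and DMSO, constant cells arm, mean over 7 MOIs (log2, n = 14 libraries per state). The 792 genes have a Pearson r of −0.862, in part because both axes share the DMSO libraries.

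With imatinib, guides against SAGA subunits, the 4 measured genes of the list of erythroid transcription factors and general transcription genes became more frequent than with DMSO. LEO1, another subunit of the PAF1 complex, rose by 4.98 ± 0.22 log2 units (mean over 7 MOIs, 14 against 14 libraries, adjusted p = 3.9e-17). GFI1B, a repressor required in the erythroid and megakaryocytic lineages, rose by 4.91 ± 0.16 (1.4e-20). The cullin scaffolds CUL3 and CUL2 rose by 3.62 ± 0.27 (1.5e-12) and 3.03 ± 0.20 (2.4e-13), and LAS1L and NCL, of ribosomal RNA processing and the nucleolus, by 3.28 ± 0.21 (9.9e-14) and 2.82 ± 0.17 (1.6e-14). TAF12 (3.02 ± 0.30, 9.4e-10), ENY2 (3.0 ± 0.44, 1.0e-06) and TRRAP (2.94 ± 0.15, 2.1e-16), all subunits of SAGA, and ACTR6 (2.77 ± 0.26, 2.2e-10), a subunit of the SRCAP remodeller, followed. Falls were few and small. The paralogous acetyltransferases CREBBP (−0.62 ± 0.14, 0.00047) and EP300 (−0.45 ± 0.10, 0.00039) fell, with the demethylase KDM4E (−0.42 ± 0.15, 0.020), ASXL1, a Polycomb-related protein (−0.38 ± 0.10, 0.0032), and BRMS1, of the SIN3 deacetylase complex (−0.37 ± 0.14, 0.028). BCR and ABL1 are not targets of this sublibrary.

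The SAGA and ADA list rose with imatinib, 17 of 20 higher, 0 lower and 3 not passing (list median 0.73 above that of all genes, camera adjusted p = 0.0022). TAF5L (1.73 ± 0.10) and TAF6L (0.99 ± 0.09) were among them. All 4 measured genes of the list named erythroid transcription factors rose (1.40 above, 7.0e-05). Besides GFI1B these were IKZF1 by 1.53 ± 0.09, MAX by 1.80 ± 0.44 and GFI1 by 0.40 ± 0.13. The size for MAX is uncertain, since its thinnest group held only 17 reads. In the MLL and menin complex 12 of 17 rose and 2 fell (0.64 above, 0.015), SETD1A by 2.30 ± 0.12, CXXC1 by 2.08 ± 0.13 and HCFC1 by 2.45 ± 0.16. All 9 genes of general transcription (1.48 above, 8.4e-05) and all 9 of integrator and exosome (1.78 above, 0.0017) rose, TAF8 by 1.89 ± 0.12 and EXOSC4 by 2.32 ± 0.20 among them. In the cell cycle engine 6 of 8 rose, and all 8 adjusted over the list alone (1.05 above, 0.023), including CDK7 (1.97 ± 0.10) and BUB1 (1.90 ± 0.20). That call was lost, with adjusted p = 0.059 with an estimated correlation, and the other 5 held. BAF chromatin remodelling had 13 rises and 0 falls of 20 (0.058), with BRD9 at 1.82 ± 0.11 and PBRM1 at 1.97 ± 0.18. Corepressors had 16 rises and 2 falls of 32 (0.42), with KDM1A, the H3 lysine 4 demethylase recruited by GFI1B, at 2.09 ± 0.16. PRC2 and HUSH silencing had 8 rises and 0 falls of 14 (0.86, 9 rises adjusted over the list alone), with RBBP4 at 2.05 ± 0.17. All 3 genes of the KEAP1 ligase rose (0.058; KEAP1 1.05 ± 0.21, RBX1 1.07 ± 0.16), as did the 3 DNA replication genes (0.32) and 4 of 5 spliceosome genes (0.42). In ubiquitin-like conjugation 5 of 8 rose (0.40), and of NF-kB signalling MAP3K7 rose by 0.66 ± 0.14 (0.77 for the list). JAK2, a cytokine receptor kinase, did not pass in either comparison (−0.08 with DMSO and −0.20 with imatinib), but with TMM over all guides it fell with imatinib (−0.50). That scaling gave 5 rises and 4 falls for PRC2, 10 and 5 for corepressors, 11 and 3 for BAF, 16 and 1 for SAGA, 10 and 3 for the MLL complex, and 5 and 2 for ubiquitin-like conjugation. Of the erythroid factors 3 of 4 still rose, and of the spliceosome genes 3 of 5.

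Of 792 genes 379 passed with imatinib, 359 higher and 20 lower, against 2 of 43 control pseudo-genes. Rank aggregation gave only 3 genes, the guide-level test 244, and the fits without either replicate number 242 and 197. TMM over all guides gave 244 rises and 211 falls and relative log expression 252 and 178, and they moved the median of all genes, 0.26, by −0.30 and −0.27. Genes that fell with DMSO and rose with imatinib numbered 282, where 146 would share both calls if the calls were independent, and 11 rose and then fell (1.41 if independent). Both comparisons use the same DMSO libraries, so chance enters both: r was −0.862 and the covariance −0.835, against −0.502 and −0.0146 in 20 simulations without effects. With disjoint DMSO replicates r was −0.784 and −0.813 and the covariance −0.806 and −0.810. Against day 0 rather than DMSO, 60 of the 359 genes lay above their starting share and 136 below it. Above every control pseudo-gene lay 29, GFI1B at 2.99 ± 0.14, CUL3 at 1.76 ± 0.25, KDM1A at 1.32 ± 0.16 and SMARCB1, a core BAF subunit, at 0.84 ± 0.16 among them.

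With rising MOI in the constant cells arm, the DMSO effect moved upwards for most genes whose slope passed the test. Per doubling of MOI the DMSO effect moved upwards for the H3 lysine 27 demethylase KDM6B by 0.28 ± 0.03 log2 units (42 libraries, adjusted p = 9.2e-08) and the TFIID subunit TAF1 by 0.71 ± 0.09 (4.2e-07). For the nucleolar deubiquitinase USP36 it moved by 0.60 ± 0.08 (7.7e-07), for the corepressor TRIM28 by 0.32 ± 0.05 (6.5e-06) and for the O-GlcNAc transferase OGT by 0.38 ± 0.06 (9.9e-06). It moved downwards for SMEK1, a regulatory subunit of protein phosphatase 4 (−0.39 ± 0.09, 0.0032), TAF6 (−0.45 ± 0.11, 0.0035), the demethylase KDM4C (−0.29 ± 0.09, 0.017), the histone gene HIST1H2BG (−0.20 ± 0.07, 0.034) and the remodeller CHD2 (−0.38 ± 0.14, 0.046). The imatinib effect moved downwards for the lymphoid and erythroid factor IKZF1 (−0.39 ± 0.05, 1.7e-07), GFI1B (−0.68 ± 0.09, 7.1e-07), the SAGA deubiquitinase subunit ATXN7L3 (−0.49 ± 0.07, 2.8e-06), KDM1A (−0.61 ± 0.09, 3.9e-06) and the ubiquitin-conjugating enzyme UBE2H (−0.31 ± 0.05, 7.9e-05). It moved upwards for TAF6 (0.64 ± 0.12, 0.00028), APOBEC2 (0.22 ± 0.06, 0.0079), SMEK1 (0.34 ± 0.09, 0.010), the splicing factor SF3B1 (0.26 ± 0.07, 0.011) and WDR5, a core subunit of the MLL complexes (0.56 ± 0.15, 0.011).

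The test of the DMSO slope passed for 127 genes, 122 upwards and 5 downwards, and that of the imatinib slope for 112, 12 upwards and 100 downwards. The median slopes of all genes were 0.06 and −0.05 and those of the control pseudo-genes 0.04 and −0.04, so part of the common direction is shared by controls. TMM over all guides gave 15 upwards and 53 downwards for imatinib, and the summed control reads 26 and 32. For DMSO fewer slopes passed with either scaling, and the median slope of all genes was 0.016 and 0.021. Without either replicate number fewer slopes passed for both effects. The guide-level test, which asks for 2 guides per gene, left 21 and 8 genes, and without the most-counted guide of each gene APOBEC2 turned to −0.027.

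The same genes were followed condition by condition. The 216 genes that fell at MOI 0.3 (constant cells, DMSO) had medians of −2.35, −2.01, −2.17, −1.98, −1.49, −1.18 and −1.09 at MOI 0.3, 1, 2.5, 5, 10, 20 and 30 in that arm. They were −1.89, −1.96, −1.05, −0.53 and −0.24 from MOI 2.5 to 30 with constant sgRNA, and −1.90, −1.86, −1.82, −1.94, −2.13 and −2.14 from MOI 1 to 30 in the low MOI control. The first of these is inflated, since the genes were picked there. The 154 genes that passed with imatinib at MOI 0.3 and were higher had medians of 1.69, 1.34, 1.60, 1.29, 0.98, 0.65 and 0.83, then 1.19, 1.24, 0.64, 0.16 and −0.29, and then 1.30, 1.34, 1.37, 1.18, 1.20 and 1.41. The zero moved with them. With constant sgRNA the control pseudo-genes had medians of 0.06, 0.12, 0.77, 1.19 and 1.76 for DMSO and −0.01, −0.13, −0.70, −0.83 and −1.40 for imatinib. Measured from these, the genes stayed at −1.95, −2.08, −1.82, −1.71 and −2.0 for DMSO and at 1.21, 1.37, 1.34, 1.00 and 1.11 for imatinib, so their move in that arm was largely one of the zero. With constant cells the gap for DMSO went from −2.37 at MOI 0.3 to −1.38 at MOI 30, and in the low MOI control it lay between −2.51 and −1.95. The pseudo-genes also spread: their standard deviation of the DMSO effect lay between 0.28 and 0.52 with constant cells, and went from 0.40 to 2.07 with constant sgRNA and from 0.31 to 1.98 in the low MOI control. Replicates correlated in the DMSO effect with r between 0.705 and 0.861 with constant cells, and fell from 0.789 to 0.277 with constant sgRNA and from 0.827 to 0.333 in the low MOI control.

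**Figure D2:**
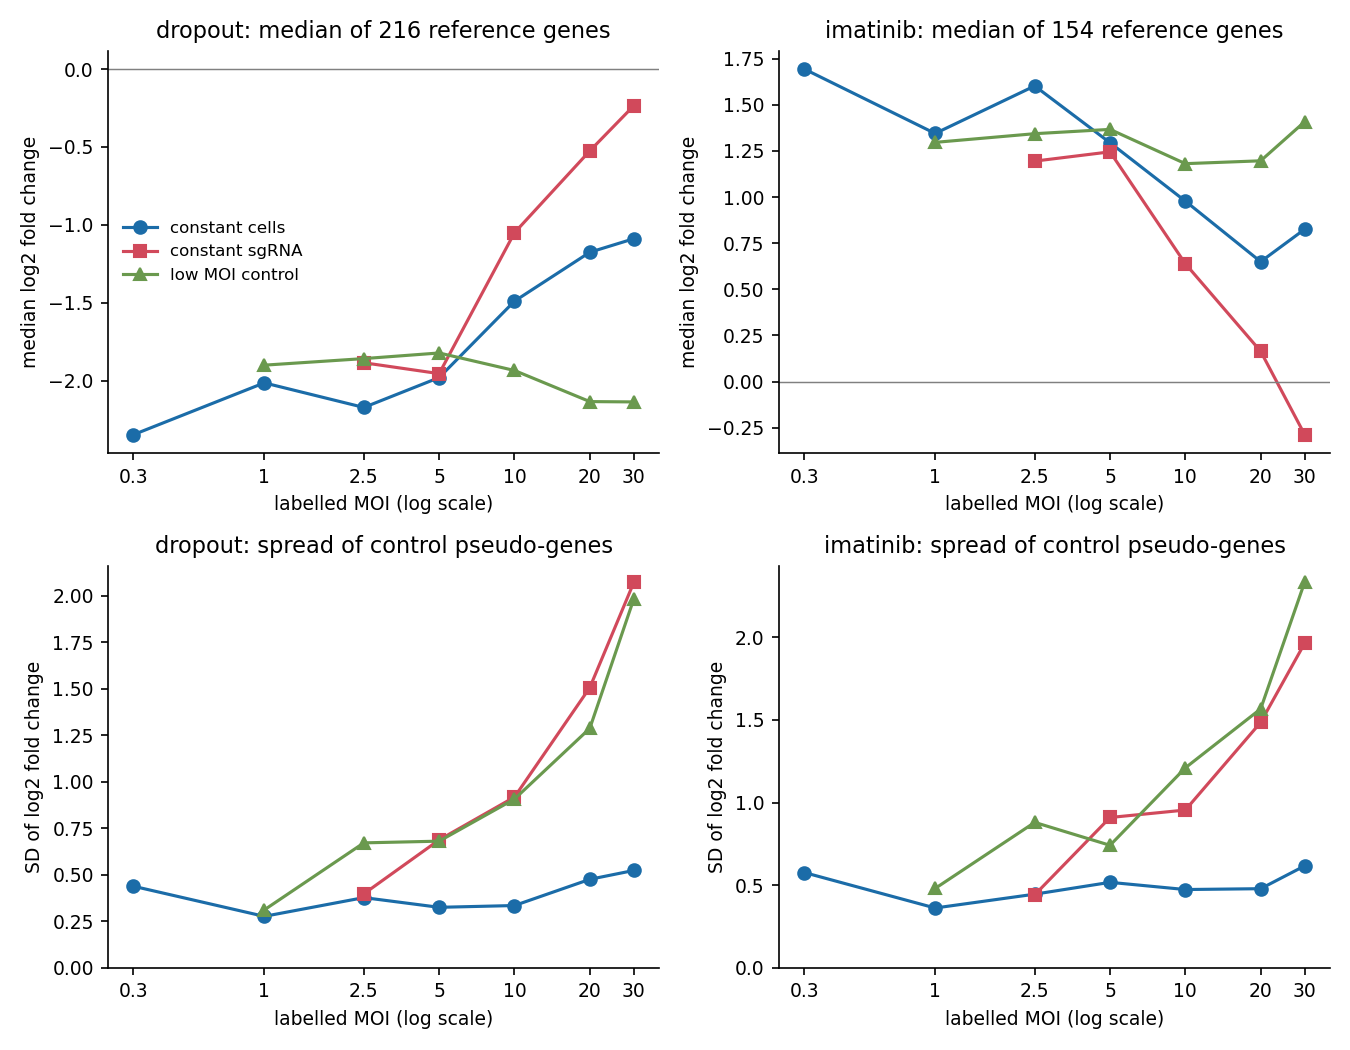
Median log2 effect of the genes called at MOI 0.3 in the constant cells arm, followed over labelled MOI in the 3 arms (216 genes for DMSO, 154 for imatinib, n = 2 libraries per group). The constant cells medians for DMSO went from −2.35 to −1.09, and those of the low MOI control from −1.90 to −2.14. Values are not taken relative to the control pseudo-genes, whose medians moved.

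With constant cells 216, 189, 227, 232, 188, 131 and 138 genes passed for DMSO from MOI 0.3 to 30 and 155, 136, 185, 213, 113, 85 and 57 for imatinib. With constant sgRNA the counts from MOI 2.5 to 30 were 178, 123, 66, 51 and 0 (236 at unadjusted p below 0.05) for DMSO and 118, 65, 40, 0 (206) and 0 (219) for imatinib. With the replicate number as a block, those for MOI 10 became 27 and 0 and that of 51 became 0, so they are weakly held. In the low MOI control they were 213, 117, 65, 20, 0 (140) and 0 (123) for DMSO and 176, 115, 59, 18, 0 (149) and 0 (128) for imatinib from MOI 1 to 30, all in edgeR's quasi-likelihood test. On simulated data with the low MOI control's DMSO counts at MOI 30, effects of 2 and 4 log2 units were found in 6.06% and 63.6% of changed genes, so power was low for all but the largest effects. Whether this alone gives the zero was not tested, and the other zeros were not simulated.

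The split into rises and falls per condition again turned on the scaling. For DMSO with constant cells the rises and falls were 0 and 216, 2 and 187, 3 and 224, 6 and 226, 28 and 160, 25 and 106, and 26 and 112. TMM over all guides gave 77 and 157, 52 and 152, 80 and 180, 104 and 162, 155 and 143, 143 and 90, and 106 and 85. The summed control reads gave 8 and 199, 12 and 158, and 5 and 150 at the last 3 MOIs. For imatinib they were 154 and 1, 133 and 3, 182 and 3, 208 and 5, 100 and 13, 76 and 9, and 54 and 3. TMM over all guides gave 76 and 19, 97 and 15, 103 and 37, 93 and 43, 94 and 99, 56 and 67, and 43 and 63. With constant sgRNA the DMSO splits were 6 and 172, 2 and 121, 18 and 48, 20 and 31, and 0 and 0. TMM over all guides turned them to 82 and 130, 44 and 80, 99 and 55, 58 and 26, and 72 and 14, and the summed control reads to 2 and 100, 0 and 103, and 1 and 229 at the last 3 MOIs. The imatinib splits there were 114 and 4, 64 and 1, and 31 and 9 from MOI 2.5 to 10, against 67 and 27, 33 and 5, and 36 and 49 with TMM over all guides. The summed control reads gave 71 and 1, 38 and 0, and 198 and 0 from MOI 10 to 30. In the low MOI control the DMSO splits were 16 and 197, 2 and 115, 1 and 64, and 0 and 20 from MOI 1 to 10. They were 94 and 168, 26 and 93, 34 and 57, and 9 and 18 with TMM over all guides, and 0 and 10 at MOI 20 with the summed control reads. Its imatinib splits were 154 and 22, 108 and 7, 54 and 5, and 17 and 1, against 131 and 73, 70 and 23, 45 and 17, and 16 and 8 with TMM over all guides.

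**Figure D3:**
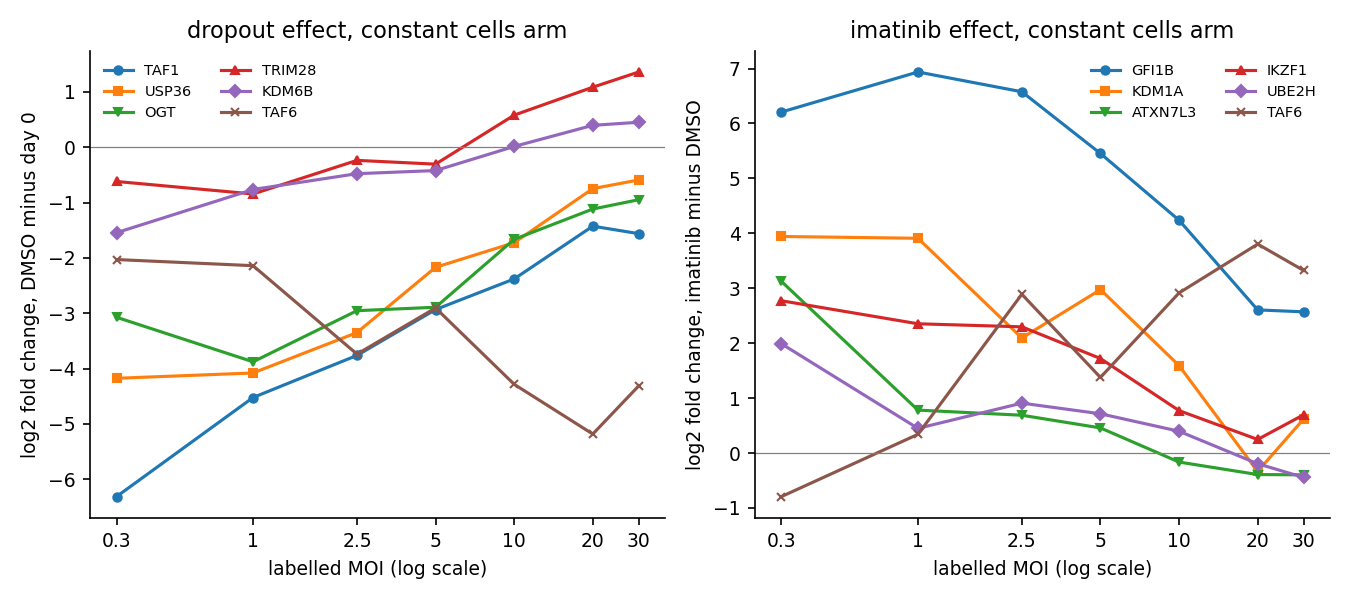
Genes past an adjusted p of 0.05 per arm and labelled MOI (n = 2 libraries per group), for DMSO against day 0 and imatinib against DMSO. With constant cells 216 and 155 genes passed at MOI 0.3 and 138 and 57 at MOI 30.

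Tested against one another at MOI 2.5 to 30, the arms differed in the most genes between the low MOI control and constant sgRNA in the main fit. With means of guide log2 values, the DMSO effect differed in more genes between the low MOI control and constant cells. Against constant sgRNA the main fit gave the following. The DMSO effect was more negative in the low MOI control for LAS1L, of ribosomal RNA processing (adjusted p = 1.3e-08), CDC73, of the PAF1 complex (2.2e-08), and EXOSC9, of the RNA exosome (3.3e-08). These 3 genes had groups without a single read, so no size is given. It was less negative for the histone gene HIST1H3J (2.43 ± 0.66, 0.0042), the DNA glycosylase MBD4 (2.19 ± 0.67, 0.011) and HIST1H3C (1.24 ± 0.41, 0.017). The thinnest groups of HIST1H3J and MBD4 held only 6 and 26 reads, so their sizes are uncertain. For imatinib LAS1L (3.1e-09), the RNA acetyltransferase NAT10 (3.5e-08) and EXOSC9 (3.5e-08), each with empty groups, were more positive in the low MOI control. HIST1H3J (−2.96 ± 0.67, 0.00056), the translocase ZRANB3 (−1.80 ± 0.41, 0.00059) and the protamine PRM2 (−1.77 ± 0.42, 0.0010) were less so. HIST1H3J again had a group with only 6 reads. Against constant cells the low MOI control had more negative DMSO effects for NAT10 (7.4e-09), CDC73 (2.3e-08) and EXOSC9 (6.9e-08). It had less negative ones for HIST1H3C (1.5 ± 0.41, 0.0094), the casein kinase subunit CSNK2A1 (1.33 ± 0.39, 0.016) and the BAF subunit ARID1A (1.16 ± 0.34, 0.017). Its imatinib effects were more positive for NAT10 (4.6e-10), LAS1L (8.0e-08) and PRPF31 (1.6e-07) and less so for the ubiquitin ligase UBR2 (−1.18 ± 0.26, 0.0011), APOBEC1 (−1.33 ± 0.31, 0.0019) and the phosphatase PPM1G (0.0082, with an empty group). Between constant sgRNA and constant cells, the methyltransferase SMYD1 (1.45 ± 0.25, 0.00023), the deubiquitinase USP46 (2.5 ± 0.50, 0.0019) and WHSC1L1, the methyltransferase NSD3 (1.35 ± 0.27, 0.0019), had higher DMSO effects. CTR9, of the PAF1 complex, had a lower one (0.028, with empty groups). SMYD1 (−1.61 ± 0.25, 2.2e-05), WHSC1L1 (−1.64 ± 0.27, 5.9e-05) and ZBTB7C (−1.26 ± 0.26, 0.0022) had lower imatinib effects, and CTR9 (0.011) and the histone-binding protein RBBP7 (2.68 ± 0.85, 0.031) higher ones. The thinnest group of RBBP7 held only 5 reads, so its size is uncertain.

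Between the low MOI control and constant sgRNA 253 genes differed for DMSO (12 higher, 241 lower) and 247 for imatinib (230 and 17). Relative log expression factors gave 25 and 127 for DMSO and 153 and 37 for imatinib, and the summed control reads 56 and 58 and 74 and 68. The median of all genes, −0.67 and 0.66, moved with these scalings by 0.40 and 0.83 for DMSO and by −0.33 and −0.72 for imatinib. Between the low MOI control and constant cells 81 genes differed for DMSO (3 and 78) and 107 for imatinib (92 and 15). Relative log expression gave 25 and 53 and 83 and 39, and TMM over all guides 15 and 68 for DMSO. The medians, −0.17 and 0.14, moved by 0.21 and −0.13 with relative log expression, and the latter by 0.16 with the summed control reads. Between constant sgRNA and constant cells 38 genes differed for DMSO (37 and 1) and 83 for imatinib (2 and 81), and the summed control reads gave 0 and 13 and 26 and 0. There the medians, 0.46 and −0.48, moved by −0.19 and 0.21 with relative log expression, by −0.94 and 0.91 with the summed control reads, and the former by 0.11 with TMM over all guides. Of 43 control pseudo-genes 12, 6, 0, 0, 3 and 4 passed in these 6 tests, and their medians, −0.75, 0.64, −0.18, −0.00, 0.54 and −0.64, can be set beside those of all genes. Without MOI 20 and 30, an alternative added after seeing the data, the counts were 52, 86, 18, 48, 0 and 2. Without the most-counted guide of each gene HIST1H3C (−1.45) and MBD4 (−0.17) changed direction. With means of guide log2 values, added after seeing the data, the differences between the low MOI control and constant cells turned for CDC73 (0.19), EXOSC9 (0.09) and PRPF31 (−0.07). Those between constant sgRNA and constant cells turned for CTR9 (0.46 for DMSO, −0.18 for imatinib). In the guide-level test HIST1H3C (−0.20) and CSNK2A1 (−0.06) turned against constant cells, and without either replicate number the 6 counts lay between 0 and 36.

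In the sorted screen the guide against ICAM1, the gene of CD54 itself, was the strongest check of the labels: it was depleted from the CD54-high gate against the low gate at both MOIs and every coverage. At MOI 0.3 ICAM1 had −4.25 ± 0.12 log2 units (mean over 3 coverages, 6 against 6 libraries, adjusted p = 1.8e-25) and −3.86, −4.47 and −4.42 at 25, 125 and 250 times coverage. It had −1.25 ± 0.11 in the high against the middle gate and 3.0 ± 0.11 in the low against the middle gate. At MOI 5 it had −3.91 ± 0.11 (3.3e-12), −3.83, −3.83 and −4.06 by coverage, and −1.25 ± 0.10 and 2.66 ± 0.10 against the middle gate. Each target here has 1 guide, so the clause of the naming rule that asks for 2 could not be applied, and every gene named below rests on a single guide.

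At MOI 0.3 guides against PTPN1 and against several genes of lysosomal nutrient signalling were among the largest rises in the high gate. This group was read from the top genes. Of the lists its members fall in, that of PI3K, AKT and mTORC1 was called and that of mTORC1 restraints was not. PTPN1, a phosphatase that restrains JAK and receptor tyrosine kinases, rose by 4.10 ± 0.13 (1.2e-24). The Ragulator subunits LAMTOR4 (3.87 ± 0.20, 9.5e-17), LAMTOR5 (3.84 ± 0.14, 1.9e-22) and LAMTOR1 (3.74 ± 0.14, 4.9e-22), and the GTPase RRAGC that they anchor at the lysosome (3.73 ± 0.14, 6.5e-22), rose with it. So did the folliculin complex, FNIP1 (3.46 ± 0.16, 1.2e-19) and FLCN (3.38 ± 0.20, 2.2e-16), and TSC1, which restrains mTORC1 (3.27 ± 0.17, 6.3e-18). The pseudokinase NRBP1 (3.72 ± 0.19, 8.8e-18) and the translation factor subunit EIF3H (3.35 ± 0.17, 4.3e-18) rose as well. After ICAM1 the largest falls were CHP2, a calcineurin B homologue (−4.21 ± 0.12, 1.8e-25), CLSTN2, a neuronal calsyntenin (−4.10 ± 0.11, 4.4e-26), RELL1 (−4.08 ± 0.14, 2.7e-23) and the NF-kB adaptor ligase TRAF6 (−4.06 ± 0.12, 1.9e-25). Next came the syntrophin SNTB1 (−3.77 ± 0.15, 1.5e-21), the golgin GOLGA5 (−3.68 ± 0.17, 4.8e-19), NUMBL, related to the Notch regulator NUMB (−3.67 ± 0.14, 1.4e-21), the Notch pathway ligase DTX1 (−3.62 ± 0.13, 1.6e-22) and the fatty acid oxidation enzyme HADHB (−3.62 ± 0.13, 1.7e-22).

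Of the lists written beforehand, mitochondrial translation stood out at MOI 0.3. In it 72 of 79 mitochondrial ribosome targets rose and 1 fell (median 1.40, camera adjusted p = 6.7e-31, 73 and 1 adjusted over the list alone). MRPL12 (2.04 ± 0.18) and MRPS17 (2.04 ± 0.21) were among the rises, and MRPL20 was the exception (−2.91 ± 0.16). All 20 aminoacyl-tRNA synthetases rose (1.24, 4.4e-10), MARS by 1.94 ± 0.24 and GARS by 1.30 ± 0.16. In oxidative phosphorylation 54 of 108 rose and 2 fell (0.51, 2.1e-09), with ATP5O at 2.76 ± 0.20 and ATP5J at −2.32 ± 0.19. SAGA and ADA had 15 rises and 1 fall of 22 (1.23, 5.4e-12), ATXN7L3 at 2.16 ± 0.14 and SUPT7L at 2.25 ± 0.16. PI3K, AKT and mTORC1, which holds the Ragulator genes, had 13 rises and 4 falls of 30 (0.36, 1.0e-11). Mediator core had 17 rises and 2 falls of 27 (1.03, 5.8e-06), with MED21 at 1.96 ± 0.25 and MED19 at 1.95 ± 0.25. Golgi transport had 23 rises and 3 falls of 48 (0.51, 4.2e-06), with SLC35A3 at 2.43 ± 0.19 and COG2 at 2.10 ± 0.22. BAF remodelling had 10 rises and 3 falls of 31 (0.34, 0.010), with SMARCE1 at 2.81 ± 0.23 and SMARCB1 at 2.60 ± 0.19. Restraints of RAS and MAPK had 10 rises and 0 falls of 36 (0.24, 0.0023), the ligase CBL at 1.43 ± 0.15 and SPRY4 at 1.00 ± 0.14. Activators from BCR-ABL to RAS had 1 rise, the adaptor CRK (0.87 ± 0.16), and 11 falls of 36 (−0.27, 0.013), SOS1 at −1.79 ± 0.29 and NRAS at −0.86 ± 0.16. The MLL complex had 2 rises and 7 falls of 18 (−0.41, 0.0075), DPY30 at −2.96 ± 0.25 and WDR5 at −1.52 ± 0.24. These 11 calls held with an estimated correlation, but camera's adjusted p was then larger for each. It was 0.011 for the mitochondrial ribosome and 0.033 for aminoacyl-tRNA synthetases. Adjusted over the list alone, the rises and falls were 60 and 2 for oxidative phosphorylation, 15 and 5 for mTORC1, 18 and 2 for Mediator core, and 24 and 3 for Golgi transport. They were 12 and 3 for BAF and 2 and 8 for the MLL complex, and as above for the others.

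The calls of 5 more lists at MOI 0.3 were lost with it. Translation initiation and elongation had 21 rises and 4 falls of 43 (camera adjusted p = 0.00032, adjusted p = 0.17 with an estimated correlation), with EIF2B1 at 2.48 ± 0.28. The Mediator kinase module had 4 rises and 0 falls of 7 (0.0037, adjusted p = 0.057 with an estimated correlation), with MED12 at 2.41 ± 0.22. The cytosolic ribosome had 20 rises and 1 fall of 90 (0.018, adjusted p = 0.093 with an estimated correlation). General transcription had 2 rises and 8 falls of 50 (0.019, adjusted p = 0.081 with an estimated correlation), with SUPT4H1 at −1.75 ± 0.22. Heme and iron had 10 rises and 1 fall of 25 (0.046, adjusted p = 0.081 with an estimated correlation), with the heme enzyme UROD at 1.58 ± 0.22. Lists that lie closest to CD54 by name were not called. NF-kB and TNF signalling had 8 rises and 4 falls of 50 (0.52, median 0.03, mean −0.02, test downwards), and the sign of its median turned with the scaling. It also turned for olfactory receptors and blood markers at both MOIs. Adhesion genes and CD54 partners had 2 rises and 5 falls of 17 (0.086), the protease ADAM10 at 1.83 ± 0.24 and the GTPase RHOA at −1.34 ± 0.22. Restraints of mTORC1 had 5 rises and 8 falls of 21 (0.87, median −0.30, mean 0.12, test upwards): FNIP1, FLCN and TSC1 rose and DEPDC5, a subunit of the GATOR1 complex, fell (−2.35 ± 0.13). Erythroid factors had 6 rises and 3 falls of 30 (0.056), with TAL1 at 2.65 ± 0.16, LMO2 at 2.29 ± 0.19 and GATA2 at −1.24 ± 0.19. Lists of genes typical of other tissues gave 16 rises and 10 falls of 372 olfactory receptors (0.77), 10 and 9 of 136 skin and hair keratins (0.91), and 0 and 1 of 19 markers of other blood lineages (0.87). Adjusted over the list alone, translation had 23 rises and 5 falls, the cytosolic ribosome 24 and 2, general transcription 1 and 8, adhesion 2 and 6, and mTORC1 restraints 5 and 10. Erythroid factors had 7 and 3, olfactory receptors 10 and 6, keratins 10 and 8 and blood markers 0 and 0.

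At MOI 0.3 the test passed for 4672 of 20528 targets, 2810 higher and 1862 lower in the high gate (6 against 6 libraries). It also passed for 106 of 1026 control guides, 10.3%, whose effects reached −3.23 and 2.24. Beyond every control guide lay 127 targets (103 higher, 24 lower), among them all the genes named in the opening sentences on MOI 0.3. With 20528 targets and only 1026 controls, some targets would lie there on each side even if both had the same spread. Lying beyond the controls is therefore no evidence by itself, least of all for the 24 falls. With p-values ranked against those of the control guides, added after seeing the data, 0 passed (6603 at unadjusted p below 0.05 in edgeR, 5206 adjusted in DESeq2, 1420 by rank aggregation). Ranks against 1026 controls are too coarse for an adjustment over 20528 targets, so this 0 does not say that no target exceeds the controls. Counts of distinct barcodes in place of reads gave 0, but targets had a median of 40 to 41 of 41 barcodes, so this measure was near its ceiling and decides nothing.

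At MOI 5, where a cell carries several guides, erythroid regulators led. GATA1, the master regulator of the erythroid lineage, rose by 4.18 ± 0.08 in the high gate (6 against 6 libraries, adjusted p = 2.1e-32) and GFI1B by 3.33 ± 0.07 (4.3e-32). The corepressor partner of GFI1B, KDM1A, rose by 2.43 ± 0.06 (6.3e-30) and MED12, of the Mediator kinase module, by 3.08 ± 0.07 (5.4e-32). NRBP1 (2.88 ± 0.09, 1.6e-25) and PTPN1 (2.36 ± 0.05, 2.7e-31) again rose. So did the zinc finger gene ZKSCAN4 (2.88 ± 0.08, 4.1e-28), the mitochondrial carrier SLC25A27 (2.44 ± 0.07, 1.7e-28), a promoter of PRDM8 (2.43 ± 0.08, 8.6e-26) and WDTC1 (2.37 ± 0.07, 3.3e-28). Below ICAM1 the largest falls were the RAS-like GTPase DIRAS1 (−3.36 ± 0.08, 7.6e-22), MRPL20 (−3.21 ± 0.08, 4.9e-31), the proton pump ATP12A (−3.13 ± 0.07, 2.7e-31) and the netrin receptor UNC5C (−2.95 ± 0.07, 2.0e-30). ZSCAN21 (−2.93 ± 0.07, 1.7e-28), the heme exporter FLVCR1 (−2.82 ± 0.06, 8.0e-32), NUMBL (−2.76 ± 0.06, 2.4e-32), the DNA repair gene XRCC3 (−2.62 ± 0.08, 4.8e-27) and the ubiquitin hydrolase UCHL3 (−2.62 ± 0.08, 5.8e-28) followed. TRAF6 had −2.53 ± 0.06 (2.7e-31).

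**Figure D4:**
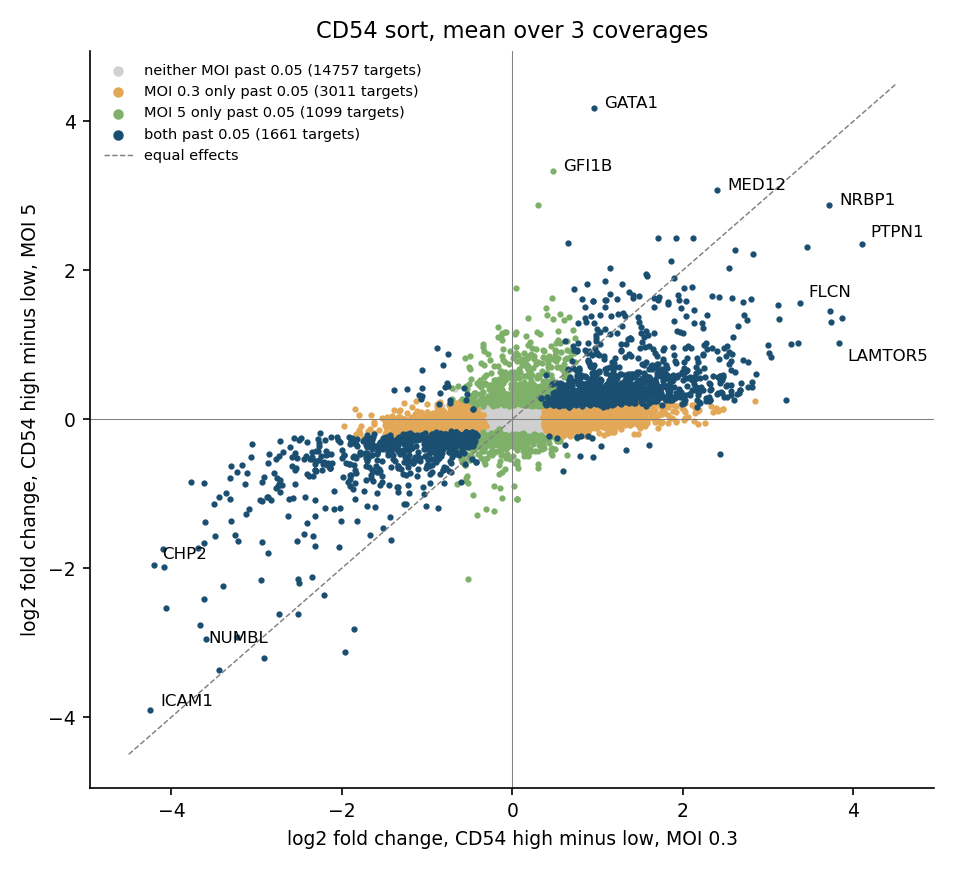
High against low CD54 gate (log2) at MOI 5 against MOI 0.3 for 20528 targets (6 against 6 libraries each). ICAM1 had −4.25 at MOI 0.3 and −3.91 at MOI 5, and 1661 targets passed at both.

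The lists called at MOI 5 were led by transcription and protein synthesis. Mediator core had 22 rises and 0 falls of 27 (median 1.01, camera adjusted p = 4.3e-61), MED30 at 1.95 ± 0.08 and MED9 at 2.12 ± 0.09. The kinase module had 4 rises and 0 falls of 7 (0.23, 1.5e-16), the cyclin CCNC at 1.04 ± 0.07. The cytosolic ribosome had 68 rises and 1 fall of 90 (0.48, 2.1e-32), RPL19 at 1.31 ± 0.09 and RPS7 at 1.41 ± 0.10. Translation factors had 25 rises and 4 falls of 43 (0.51, 1.7e-23), EIF2B2 at 1.72 ± 0.08 and EIF3C at 1.59 ± 0.07. The mitochondrial ribosome had 65 rises and 1 fall of 79 (0.43, 1.2e-19), tRNA synthetases 14 rises and 0 falls of 20 (0.33, 3.4e-09), with SARS at 1.61 ± 0.10, and oxidative phosphorylation had 50 rises and 3 falls of 108 (0.20, 1.9e-08). SAGA and ADA had 15 rises and 1 fall of 22 (0.59, 1.5e-17), TAF12 at 1.69 ± 0.09. Erythroid factors had 11 rises and 2 falls of 30 (0.06, 2.5e-16), LMO2 at 1.40 ± 0.06 and TAL1 at 1.26 ± 0.07. Spliceosome (32 rises and 3 falls of 54, 0.38, 2.0e-16), proteasome (25 and 0 of 42, 0.43, 4.5e-13) and DNA replication (24 and 2 of 44, 0.31, 4.4e-10) were called, with SRSF1 at 1.62 ± 0.09, PSMB6 at 1.37 ± 0.10 and the licensing factor CDT1 at 1.40 ± 0.12. PI3K, AKT and mTORC1 had 11 rises and 1 fall of 30 (0.13, 2.6e-14), RRAGC at 1.46 ± 0.06. Restraints of mTORC1 had 6 rises and 3 falls of 21 (3.1e-04, median −0.01, mean 0.21, test upwards), FNIP1 at 2.32 ± 0.06, and restraints of RAS had 7 rises and 0 falls of 36 (0.04, 0.0054), LZTR1 at 0.67 ± 0.07. Golgi transport had 17 rises and 2 falls of 48 (0.11, 0.0054), COPB1 at 1.24 ± 0.11, and the MLL complex 3 rises and 6 falls of 18 (−0.09, 0.0013). RAS activators had 0 rises and 8 falls of 36 (−0.04, 0.010), GAB2 at −0.86 ± 0.11 and BCR at −0.87 ± 0.13. Adjusted over the list alone, the rises and falls were 22 and 1 for Mediator core, 5 and 0 for its kinase module, 72 and 1 for the cytosolic ribosome and 26 and 5 for translation factors. They were 69 and 1 for the mitochondrial ribosome, 16 and 0 for tRNA synthetases, 55 and 3 for oxidative phosphorylation, 16 and 1 for SAGA and 12 and 3 for erythroid factors. They were 35 and 3 for the spliceosome, 26 and 0 for the proteasome, 27 and 2 for replication, 12 and 2 for mTORC1, and 7 and 3 for its restraints. They were 8 and 0 for restraints of RAS, 20 and 5 for Golgi transport, 3 and 9 for the MLL complex and 0 and 11 for RAS activators. All 18 calls held with an estimated correlation, but camera's adjusted p was then larger for each, and 9.8e-05 for Mediator core. The lists of NF-kB (2 rises and 2 falls, 0.16), adhesion (2 and 4) and the 3 groups of other tissues (7 and 3, 2 and 2, 0 and 0) were not called.

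**Figure D5:**
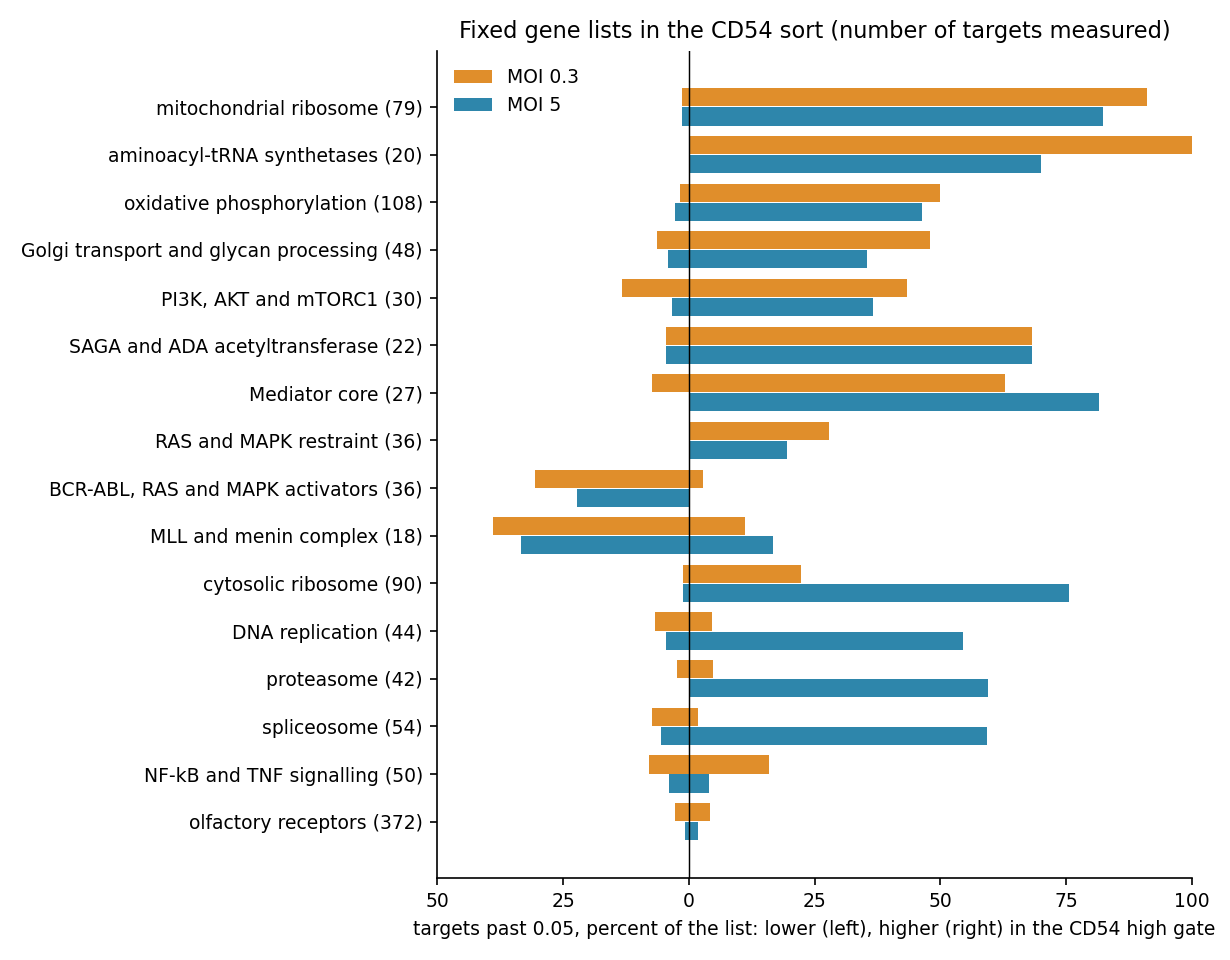
Members of the gene lists shown that were higher or lower in the CD54-high gate at MOI 0.3 and MOI 5 (edgeR, adjusted p below 0.05). Mitochondrial ribosome targets rose 72 and 65 times of 79, olfactory receptors 16 and 7 times of 372.

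At MOI 5 the test passed for 2760 targets, 1731 higher and 1029 lower, and for 36 control guides (3.51%), and 185 targets (99 higher, 86 lower) lay beyond every control. Against the middle gate 1111 targets (745 and 366) moved in the high gate and 937 (367 and 570) in the low gate, compared with 1802 (1542 and 260) and 1964 (1180 and 784) at MOI 0.3. Both MOIs called 1661 targets, 1624 with the same sign, 1004 higher and 620 lower, where 237 and 93.3 would be shared by independent calls. Among them the effects at MOI 5 had a slope of 0.378 on those at MOI 0.3. At higher coverage more targets passed: 1209, 2436 and 3136 at 25, 125 and 250 times coverage at MOI 0.3, and 845, 1587 and 1945 at MOI 5 (2 against 2 libraries each). With p-values ranked against those of the control guides 0 passed (4767 at unadjusted p below 0.05 in edgeR, 3142 adjusted in DESeq2, 1108 by rank aggregation). As at MOI 0.3, such ranks are too coarse for this 0 to speak against single targets.

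The test of the difference between the MOIs passed for 3611 targets, 1457 higher and 2154 lower at MOI 5 (12 against 12 libraries). The difference was positive for CLSTN2 (2.34 ± 0.11, 4.5e-18), the synapsin SYN3 (2.56 ± 0.13, 4.5e-18), SNTB1 (2.91 ± 0.16, 1.1e-16), CHP2 (2.24 ± 0.14, 1.5e-15) and BBC3, the apoptosis gene PUMA (2.25 ± 0.14, 1.9e-15). It was negative for LAMTOR5 (−2.82 ± 0.14, 4.5e-18), the deubiquitinase BAP1 (−2.92 ± 0.17, 6.8e-16), LAMTOR1 (−2.43 ± 0.14, 1.1e-15), and ATP5J2 and PTCD1, which share 1 guide (−2.29 ± 0.13, 2.2e-16 each). Targets called at both MOIs had smaller effects at MOI 5 in general (slope 0.378), so a difference need not mean an opposite direction. CLSTN2, SNTB1 and CHP2, which fell at MOI 0.3, and LAMTOR5 and LAMTOR1, which rose there, moved towards 0 without changing direction. ICAM1 did not pass (0.33 ± 0.14, 0.089). Of the control guides 74 passed, and DESeq2 gave 4155 targets.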

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

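Of the tests in this part, the share of imatinib rises above day 0, the 2 tests of the arms, the correlation of control guides between MOIs and the test on shared guide ends were chosen only after the results they examine had been seen. So were the summed control reads and the arms without MOI 20 and 30. The ratio of imatinib to DMSO effects, GC content and the regroupings were not.

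A test of the difference itself brought 9 results here. The change from day 0 to day 14 in DMSO varied with MOI for 127 genes, and the change between imatinib and DMSO for 112. Between constant sgRNA and constant cells 38 genes differed with DMSO and 83 with imatinib, between the low MOI control and constant cells 81 and 107, and between the low MOI control and constant sgRNA 253 and 247. Between MOI 5 and MOI 0.3 of the CD54 screen 3611 targets differed.

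Labels were regrouped to ask whether chance could give as many genes, with a model that adds up the factors except for the slopes, so only the counts of the slopes are those of the report. Only the real split, 1 of 100, gave as many genes for the DMSO effect (431 against 0 in the highest other split). The same held for the imatinib effect (279 against 0) and the DMSO slope (127 against 121). For the imatinib slope 4 of 100 splits gave as many, the real one included, and another split reached 119 against the real 112. For the arms, in the order above with DMSO before imatinib, only the real split gave as many (1 of 100 each). The counts were 6 against 1, 21 against 15, 14 against 2, 24 against 4, 117 against 86 and 134 against 124. In the CD54 screen the real split also gave the most, with 4219 against 2 at MOI 0.3 and 2319 against 89 at MOI 5 (1 of 50 each). For the difference it gave 3766 against 930 (1 of 30). So few splits make chance less likely but do not exclude it, least of all where another split came close. These tests were not adjusted for one another.

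The rise of most genes with imatinib may come from fewer divisions in the drug, which would leave depleted guides closer to their starting share. For the 282 genes that fell with DMSO and rose with imatinib, this needs a ratio of the imatinib to the DMSO change, each against day 0 from other replicates, above 0, and the median was 0.257 (interval 0.203 to 0.290, 70 at or below 0). That the ratio lies below 1 follows from how these genes were chosen and supports nothing. Fewer divisions cannot hold for all 359: 8.08% of them (29 genes, GFI1B, LEO1, CUL3 and KDM1A among them) lay above day 0 beyond every control, where fewer divisions would leave them at or below their start. Protection of those cells from imatinib is a hypothesis for this part, and no growth rate was measured here.

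The wave of lower DMSO effects in the low MOI control against constant sgRNA, with LAS1L and EXOSC9 in front, was weighed against 2 technical explanations. A shift of the zero could account for the common direction, since control pseudo-genes shared it. The median of all genes lay 0.075 log2 units above theirs (−0.67 against −0.75, standard error of the latter 0.12), and with the summed control reads 58 were lower and 56 higher. With TMM over all guides, which does not rest on the controls, 263 of 269 were still lower, so the scale leaves the direction unsettled. Beyond every control lay 109 lower and 11 higher genes, and the cause for these stays open. With 792 genes and only 43 pseudo-genes, as few as 11 higher genes can lie there without effects. Without MOI 20 and 30, where libraries were thinnest, 52 genes were called in place of 253. Thin libraries may be behind this, but fewer libraries and the loss of the highest labelled MOIs would lower the count as well. The drop alone therefore cannot decide. That cells with many guides lose selection on each of them remains an untested biological explanation.

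In the CD54 screen at MOI 0.3, control guides passed at 10.3%, and their effects could come from chance clones, base composition or binding elsewhere. Their effects correlated between the separately infected MOIs with r = 0.467 (permutation p = 1e-04, the smallest 10000 draws can give). Without the 10 farthest guides r was 0.306, and the rank correlation of all control guides was 0.232. This argues against clones that grew by chance, and GC content explained r² = 0.000483 of the effects. Over 258 pairs of guides for different loci that share the 11 bases next to the PAM, effects correlated with r = 0.270 (permutation p = 1e-04). At MOI 5 r was 0.0963 (permutation p = 0.050, at the edge of the threshold). Pairs sharing the far end had −0.103 and −0.117. All these pairs came from targeting and control guides together, so they do not measure the control guides alone. Off-target binding through the seed is thus only a candidate explanation, better supported at MOI 0.3. It stays open for CHP2, CLSTN2 and RELL1, whose single guides fell as far as the one against ICAM1.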

How the results depend on the processing

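Settings added after seeing the data were the summed control reads, the counts beyond the controls, p-values ranked against controls, means of guide or barcode log2 values, and the arms without MOI 20 and 30. The planned addition of MiniSeq reads was not run, since those samples have no column here. Distinct barcodes at MOI 5 could not be fitted, as 75.1%, 93.8% and 97.1% of targets had all 41 barcodes in every library. Over all settings 348 counts stayed within 1.5 times the main value and 269 did not. Of values for genes and lists 7886 kept direction and side of the threshold, 1509 fell below it, 55 passed it and 52 changed sign. A further 6 list calls were lost only with an estimated correlation. The cause was not tested unless given. Arms stand in the order sgRNA minus cells, low MOI control minus cells, low MOI control minus sgRNA, with DMSO before imatinib in each.

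TMM over all guides gave 589 genes for DMSO (306 of the 379 shared), 61 and 68 for the slopes, 112 and 126 for sgRNA minus cells. Per condition it gave, with constant cells, 298 and 233 for DMSO at MOI 10 and 20 and 95, 136, 193 and 106 for imatinib at MOI 0.3, 5, 10 and 30. With constant sgRNA it gave 154, 84 and 86 for DMSO at MOI 10, 20 and 30 and 38 and 85 for imatinib at MOI 5 and 10. Relative log expression gave 587 for DMSO, 82 for its slope, 16 and 30 for sgRNA minus cells, and 152 for DMSO in low MOI control minus sgRNA. GFI1 turned to 0.29 with both scalings. The summed control reads gave slopes of 65 and 58, 13 and 26 for sgRNA minus cells, and 114 and 142 for low MOI control minus sgRNA. Per condition they gave 75 for imatinib with constant cells at MOI 0.3, 102, 103 and 230 for DMSO and 72, 38 and 198 for imatinib with constant sgRNA at MOI 10, 20 and 30. In the low MOI control they gave 53 and 47 at MOI 10 and 10 for DMSO at MOI 20.

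Rank aggregation gave 1 gene for DMSO and 3 for imatinib. The cause was not tested, and in simulation it found 53.7% to 95.5% of changes. It gave 1420, 690 and 786 targets at MOI 0.3 (high against low, high against mid, low against mid) and 1108, 554 and 547 at MOI 5. The guide-level test gave 244 for imatinib, 21 and 8 for the slopes, 0 and 0 for sgRNA minus cells, 47 for imatinib in low MOI control minus cells, and 86 and 62 for low MOI control minus sgRNA, with HIST1H3C at −0.20 and CSNK2A1 at −0.061. Without each gene's most-counted guide the slopes had 40 and 41 and the first 4 arm results 0, 12, 218 and 171. NCOA6 (−0.29), CHUK (−0.96), APOBEC2 (−0.027), HIST1H3C (−1.45) and MBD4 (−0.17) turned. Means of guide log2 values gave 74 and 47 for the slopes and 0, 1, 23, 16, 12 and 28 for the arms. CTR9 was at 0.46 (DMSO) and −0.18 (imatinib), CDC73 at 0.19, EXOSC9 at 0.090 and PRPF31 at −0.069, and these genes had groups without reads. DESeq2 gave 94, 126, 148 and 176 for the first 4 arm results. Without MOI 20 and 30 the arms had 0, 2, 18, 48, 52 and 86. Beyond every control lay 227 genes for DMSO and 127 and 185 CD54 targets.

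In the CD54 screen the barcode-set test gave 1586, 245 and 338 at MOI 0.3, 1046, 280 and 222 at MOI 5 and 1005 for the difference. Means of barcode log2 values gave 3461 and 3424 against mid at MOI 0.3, with SNRPD3 at 0.000064. Without coverage 125x the 4 results against mid had 1000, 1017, 631 and 518. Without 250x they had 952, 970, 632 and 477 and high against low at MOI 0.3 had 3106. Without the most-counted barcode set the 4 had 1039, 1152, 684 and 541. P-values ranked against controls, too coarse to speak against single targets, gave 0 and 0. Distinct barcodes, of which targets had a median of 40 to 41 of 41 and only 7.83%, 15.5% and 28.9% of targets had all in every library at 25x, 125x and 250x, gave 0 for each of the 3 comparisons at MOI 0.3, for the difference and for 25x, 125x and 250x. Signs turned close to 0 there: 0.00061 (ICAM1, CHP2, CLSTN2, TRAF6, NUMBL, HADHB, RBBP7, ATP5J), −0.0053 (FNIP1, MALT1, MTF2, SRC), −0.0112 (TNIP1, NFKB1, SUZ12, MED13, SPRY4, MAD2L1), −0.0113 (CDK8), −0.0115 (E2F4), −0.029 (DPM1), −0.0295 (BIRC6), 0.0065 (DEPDC5), 0.0128 (RBL1), −0.0328 (CCNA2), 0.0124 (TFDP1), 0.0439 (CDC7), −0.0362 (RPL36A), 0.0076 (TAF6) and 0.0131 (RHOA). ICAM1 was at 0.0042 against mid, 0.0089 at 25x and 0 at 125x and 250x, and ATP5J2 and PTCD1 at 0.0038 in the difference.

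Replicate numbers carried a weak pairing in part of the sublibrary. Deviations correlated above 0.1 in 1 of 18 CD54 pairs and 15 of 54 sublibrary pairs, and below −0.1 in 1 sublibrary pair. Those of DMSO and imatinib at day 14 had r from 0.069 to 0.268 with constant sgRNA and from 0.062 to 0.131 with constant cells. In the low MOI control those of day 0 and day 14 DMSO had r from 0.043 to 0.156. The main fits had no replicate block, so such shared deviations were left out of them. With the replicate number as a block 378 genes passed for DMSO, 377 for imatinib, and 4931, 2765 and 3698 targets at MOI 0.3, MOI 5 and in the difference. The block moved only 6 counts, all of single conditions: with constant sgRNA 27 (DMSO) and 0 (imatinib) at MOI 10 and 0 (DMSO) at MOI 20, in the low MOI control 39 (imatinib) at MOI 5 and 12 and 4 (DMSO and imatinib) at MOI 10.

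Without replicate 1 or 2, where a lone library is assumed to vary like the others, the lowest and highest counts were 256 and 280 for DMSO, 197 and 242 for imatinib, 35 and 40 and 12 and 13 for the slopes, and 0 and 1, 0 and 0, 6 and 9, 8 and 9, 12 and 29, and 17 and 36 for the arms. For CD54 they were 2916 and 3777, 648 and 1264, and 1041 and 1054 at MOI 0.3, 1768 and 1825, 553 and 573, and 440 and 454 at MOI 5, and 1852 and 2650 for the difference. Without each single library they were 691 and 1037 at 25x and 1441 and 2673 at 125x (MOI 0.3). With constant cells they were 115 and 232, 138 and 263, 147 and 278, 90 and 299, 45 and 377, and 16 and 339 for DMSO from MOI 1 to 30, and 86 and 181, 109 and 240, 103 and 230, 50 and 280, 0 and 355, and 0 and 325 for imatinib. With constant sgRNA they were 87 and 228, 33 and 183, 0 and 467, 0 and 495, and 0 and 477 for DMSO, and 60 and 176, 16 and 147, 0 and 453, 0 and 504, and 0 and 477 for imatinib. In the low MOI control they were 118 and 249, 46 and 186, 9 and 143, 0 and 176, 0 and 243, and 0 and 70 for DMSO, and 98 and 223, 58 and 190, 17 and 168, 0 and 187, 0 and 243, and 0 and 92 for imatinib.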

Other observations

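The test on the neighbours of ICAM1 was chosen only after the result was seen, and that on growth genes was not. Corepressor genes went both ways in the CD54 screen. At MOI 0.3, 13 of 40 rose and 12 fell (camera adjusted p = 0.14), and at MOI 5, 8 rose and 14 fell (0.35). KDM1A and its scaffold RCOR1 rose (1.93 ± 0.15 and 2.43 ± 0.06 for KDM1A at MOI 0.3 and 5, 1.66 ± 0.09 for RCOR1 at MOI 5), while HMG20B, a further subunit of the CoREST complex, fell (−3.22 ± 0.21 and −1.64 ± 0.09), as did SUDS3 of the SIN3 complex (−3.09 ± 0.17 and −1.20 ± 0.07). The ubiquitin E2 enzyme UBE2H and MAEA, of the CTLH ubiquitin ligase, rose at MOI 5 (0.77 ± 0.09 and 0.43 ± 0.07), in a list of which 7 of 33 rose and 2 fell (0.39).

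Chaperones and RNA processing went both ways too. HSPA9, the mitochondrial HSP70, rose at both MOIs (1.58 ± 0.27 and 1.93 ± 0.09) and the chaperonin subunits CCT4 (−1.24 ± 0.24 at MOI 0.3) and CCT3 (−0.60 ± 0.09 at MOI 5) fell, with 3 rises and 5 falls of 23 at MOI 0.3 (0.87) and 3 and 8 at MOI 5 (0.59). Of integrator and exosome genes 4 rose and 6 fell of 29 at MOI 0.3 (0.38) and 2 rose and 7 fell at MOI 5 (0.073), INTS3 at −0.54 ± 0.08. The transcription factors STAT5A and STAT5B, close paralogs, moved apart (0.91 ± 0.14 and −1.21 ± 0.28 at MOI 0.3; 0.43 ± 0.07 and −0.99 ± 0.09 at MOI 5), and RB1 rose at both (1.44 ± 0.14 and 0.36 ± 0.07).

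Growth genes filled more lists at MOI 5. For 230 targets of the ribosome, spliceosome, proteasome and DNA replication the median effect was 0.09 at MOI 0.3 and 0.43 at MOI 5, while their guides in the middle gate were 2.77 log2 units more frequent at MOI 5 (random targets 0.03 to 0.11; olfactory receptors 0.017). The 4 groups had 2.69, 2.92, 2.84 and 2.82. A candidate explanation for the added calls is that guides of growth genes are lost less at MOI 5, which leaves more reads. More reads alone would not move a median effect, and the cause of that move was not tested. From MOI 0.3 to MOI 5 the median went from 0.40 to 0.48 for the ribosome and from −0.13 to 0.38 for the spliceosome. It went from 0.01 to 0.43 for the proteasome and from −0.06 to 0.31 for DNA replication.

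Targets next to ICAM1 on chromosome 19 (hg38, 10271120 to 10286615) fell with it more often than others at MOI 0.3: 5 of 9 within 50 kb against 9.05% of 20518 (1-sided Fisher exact test, p = 0.000562). ICAM4 (−2.03), ZGLP1 (−1.43), RAVER1 (−1.34 and −1.16 at its 2 promoters) and a promoter of ICAM5 (−0.86) fell, while the other ICAM5 promoter (1.20) and MRPL4 (0.58) rose. At MOI 5 ICAM4 (−1.71), ZGLP1 (−0.40), RAVER1 (−0.91 and −0.28) and FDX1L (−0.48, not passing at MOI 0.3 with 0.46) fell, while that ICAM5 promoter (−0.09) and MRPL4 (−0.00) did not pass and the other ICAM5 promoter rose (0.54). Silencing that reaches the ICAM1 promoter from guides bound nearby may be the cause, as a hypothesis from these data.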
